A study of Mus musculus with 4 samples.

How the data were processed

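The data are single-cell RNA libraries made on the 10x Chromium platform, which tags each captured RNA molecule with a unique molecular identifier (UMI), from the periodontal ligament of 11-week-old mice with ligature-induced periodontitis. Per the labels' protocols, gingiva was removed, the molars of the ligature side were extracted, and ligament cells were released with Liberase and trypsin. Each of the 4 libraries pooled cells of 5 mice, per the labels. The submitters' processing notes name Cell Ranger 7.1.0, Seurat without a version and the mouse build mm10. The authors deposited, for each library, a matrix of whole-number counts, the UMIs of 32306 features in each barcode. The features include 21 sequences that are not mouse genes, among them a bacterial beta-galactosidase reporter, and these entered no comparison of mouse genes. Whether reads within introns were counted is not given in the sources used here.

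Groups were taken from the genotype and the day in the labels: wild type and Col6a2 knockout (Col6a2-KO), each at day 1 and day 3 after ligature placement, with 1 library per group. The replicate numbers in the labels follow the day and pair nothing. With 1 library per group no test between groups was run and no p-value is given. Genotype was compared within each day and day within each genotype, and an additive model of genotype and day was not fitted, since its only residual degree of freedom would be the difference between the days. Intervals are 95% intervals and cover counting error only, not the spread between mice or preparations. Library preparation and group cannot be told apart.

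Barcodes were kept with at least 200 detected genes, at least 500 UMIs and at most 10% mitochondrial UMIs. Scrublet, as implemented in Scanpy 1.11.5, scored doublets in each library. Its automatic threshold marked 1 of 5843 cells in wild type at day 1 and 0 of 7076, 11111 and 10117 cells in the others, so it was not used, and the cells with the highest scores were removed instead, 0.8% of barcodes per 1000 barcodes. This removed 342 cells from wild type and 493 from Col6a2-KO at day 1, and 1100 and 912 at day 3. Barcodes with under 200 genes, which the gene minimum removed, carried mostly hemoglobin RNA: 96.9%, 97.7%, 97.6% and 97.5% of their UMIs in wild type and Col6a2-KO at day 1 and wild type and Col6a2-KO at day 3.

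The kept cells of the 4 libraries were clustered together without batch integration. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes were chosen within libraries among genes seen in at least 10 cells, values were scaled with a ceiling of 10, and 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 were used (seed 0). Collagen VI, sex-linked, hemoglobin, mitochondrially encoded and antigen receptor genes were left out of the variable genes. A cluster took the name of 1 of 17 cell classes if at least 3 of that class's fixed markers, and at least 25% of them, were detected in 10% or more of its cells at 2-fold or more over the other clusters. This share of 25% was set after the data had been seen. The class considered was the 1 with the highest mean log2 fold of its markers. For 2 further reasons a cluster stayed unnamed, both read from the 10 genes furthest above all other cells. Markers of another class there exceeded its own by more than 1, or its cells were shallow for their libraries and it had none of its own there. Clusters with 3 or more markers of another class among their 10 leading genes, ranked against the median cluster or against all other cells, were divided again at resolution 0.5. The parts were named by the same rule and could keep such markers, as 3.4, 7.2, 7.5 and 7.7 did. The 1 cluster left unnamed, 10, had 4 of the 32 markers of its closest class, under the share of 25% (it was led by Gm10800, Gm10801 and neuronal genes), held 1.36%, 0.456%, 0.629% and 1.01% of cells in the order above. How the mixed clusters divide depended on the random start and on the linear algebra library's processor setting, so both were held fixed. Tables first made under another processor setting were discarded, and another random start was run as an alternative. The names are rebuilt here from markers and are not the authors' annotation.

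UMIs were summed per library and class for the 4 named classes with the most cells in their smallest library: neutrophils, monocytes and macrophages, fibroblasts and endothelial cells. Levels are in CPM, a gene's UMIs as a part of the summed UMIs of that library and class, scaled to the same total throughout. A log2 ratio used a pseudocount of 0.5 UMI on each sum. Genes 2-fold or more apart were counted among genes with at least 100 UMIs over the 4 libraries, or at least 50 over the 2 libraries of a day. For 24 gene lists, the median log2 ratio was taken over members with at least 50 UMIs in the class, and its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these libraries and is not a test. List members were counted as higher or lower at 1.5-fold. Half-widths after ± are 95% half-widths from the standard deviation of 200 Poisson redraws of the counts, taken as normal. The redraws treat UMIs as independent, so they do not cover UMIs gathered in few cells. Intervals of CPM and of ratios are exact Poisson intervals, and those of shares are exact (Clopper-Pearson) binomial intervals. Against a count of 0, folds are bounds taken at a floor of 3 counts per library. For shares of cells with a UMI, cells were also thinned to 1000 UMIs each.

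Named genes followed a rule fixed, with the lists and markers, before the data were examined. In each main class it takes the 6 genes highest and the 6 lowest in Col6a2-KO, ranked by the day nearer to no difference, at 1.5-fold or more the same way on both days, and the 3 highest and 3 lowest of each day. For time it takes the 6 highest and 6 lowest at day 3 in both genotypes, and for each list up to 4 members with the largest mean absolute ratio. A named gene needed at least 100 UMIs in the class and, in the library where the class held it highest, a level of at least 25% of that in any other named class. This limits the naming of free RNA from other cell types, but in other libraries a named gene can lie under that share. Sex-linked, mitochondrially encoded, ribosomal protein, hemoglobin and antigen receptor genes and gene models named only by number were not ranked, and list members did not need to pass the 25% rule. A gene named outside this rule is said to have been chosen after its values were seen. The text names some of the genes that this rule takes, and 1 of those taken for time is not reported here.

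The steps that compare genes were tested on simulated counts with 100 genes changed 4-fold and 100 changed 3-fold. Among 8256 genes simulated for neutrophils, 97% and 93% of these were called 2-fold apart on both days. The shares were 86% and 83% for monocytes and macrophages (6019 genes), 87% and 91% for fibroblasts (10100 genes) and 92% and 85% for endothelial cells (10137 genes). Unchanged genes were called in endothelial cells only, 1 of 9958. The simulated counts had Poisson error alone, around a mean profile shared by the libraries. They held no variation between mice, preparations or cells, so these shares do not bound false calls in the real libraries.

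The alternatives fixed beforehand were 500 detected genes, 20% and 5% mitochondrial share, no doublet removal, Leiden resolutions 0.5 and 2, classes by per-cell marker score, shares of non-neutrophil cells, median-of-ratios size factors, means over cells, a pseudocount of 5 UMIs, no minimum beyond 1 UMI, a minimum 4 times higher, and leaving out genes under 25% of another class's level. Alternatives chosen after seeing the data left out each gene's highest cell, restricted day 3 to cells with a Y-linked UMI and no Xist UMI, kept only some clusters of a class, or divided the mixed clusters from another random start. The list medians over time were added to the results after seeing the data. Coordinates are from GENCODE vM21 on GRCm38 (mm10). Work was done in Python 3.11.15 with numpy 2.4.6, SciPy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.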

Results

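Cells of the mouse periodontal ligament, the connective tissue that holds a tooth in its socket, were profiled 1 and 3 days after a ligature was tied around the molars to start periodontitis. The mice were wild type or lacked Col6a2, which encodes the alpha-2 chain of type VI collagen, a beaded-filament collagen built from alpha-1, alpha-2 and a further alpha chain. The comparison addresses whether loss of this collagen alters the inflammation and tissue damage that follow ligature placement. There were 4 groups of 1 library each, with cells of 5 mice pooled per library. The libraries held 7320 barcodes and 39993471 UMIs (wild type, day 1), 8714 and 38430375 (Col6a2-KO, day 1), 12370 and 48905874 (wild type, day 3), and 11274 and 43640368 (Col6a2-KO, day 3). After filtering, 5501, 6583, 10011 and 9205 cells remained in that order, with median depths of 3247, 2191, 2308 and 2349 UMIs and 860, 779, 716 and 729 genes per cell. No group had a replicate, so each difference below is between 2 libraries and none was tested. Xist, the noncoding RNA of the inactive X chromosome, was found in 714 of the Col6a2-KO day 3 cells and in 2, 2 and 1 cells of the other libraries in the order above, so the day 3 libraries differ in this as well as in genotype. Some day 3 values are therefore also given over cells with a Y-linked UMI and no Xist UMI. This restriction also removed cells in which no Y-linked UMI was seen. It left 1999 of 7233 neutrophils and 179 of 354 fibroblasts of wild type at day 3. Day 1 cells were not restricted, so ratios over time under it set selected day 3 cells against all day 1 cells.

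Col6a2 RNA was near absent from the knockout libraries, in the direction of their labels. Col6a2 (ENSMUSG00000020241, chromosome 10, 76595762 to 76623630 on the minus strand of GRCm38) stood in fibroblasts at 125 CPM (95% interval 116 to 136, 616 UMIs) in wild type at day 1 and 4.05 CPM (2.59 to 6.02, 24 UMIs) in Col6a2-KO. At day 3 the values were 514 CPM (488 to 540.4, 1480 UMIs) and 2.16 CPM (0.791 to 4.69, 6 UMIs). Wild-type fibroblasts thus held 31.0-fold more (20.6 to 48.7) at day 1 and 238-fold more (109 to 650.1) at day 3. In mural cells, the pericytes and smooth muscle of vessel walls, the corresponding ratios were 26.5 (3.98 to 1125, on 1 knockout UMI) and 145 (39.4 to 1211, on 2). A UMI of Col6a2 was seen in 44.2% and 55.6% of wild-type fibroblasts at day 1 and day 3, and in 1.81% and 1.83% of knockout fibroblasts. Neutrophils, which should lack the gene, showed 0.193%, 0%, 0.470% and 0.0146% in wild type and Col6a2-KO at day 1 and wild type and Col6a2-KO at day 3. Their median depths were 3058, 2094, 2190 and 2205 UMIs against 9003, 2331, 6381 and 7026 in fibroblasts, and thinned to 1000 UMIs the fibroblast shares were 10.4%, 0.461%, 25.7% and 0.327%, leaving out 56, 293, 43 and 21 shallower cells.

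The partner chains of Col6a2 were still transcribed in knockout fibroblasts. Col6a1 was 1.32-fold the wild-type level (1.21 to 1.45) at day 1 and 0.762-fold (0.708 to 0.819) at day 3. Col6a3 was 1.35-fold (1.22 to 1.51) and 0.910-fold (0.855 to 0.968). With mixed clusters divided from another random start, a setting chosen after seeing the data, wild-type fibroblast Col6a2 was 115 and 419 CPM. There, a cluster of 197 cells closest to fibroblasts, with Col6a2 among its leading genes, was left unnamed and out of the class. All 3 chains stood higher at day 3 than at day 1 in wild-type fibroblasts, as the plot of collagen VI levels shows.

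**Figure D1:**
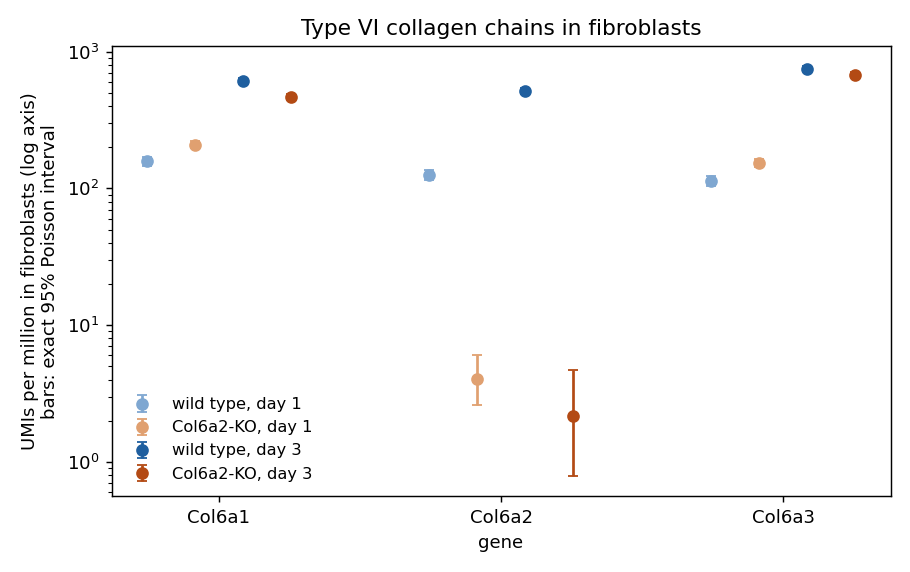
CPM of Col6a1, Col6a2 and Col6a3 in fibroblasts of the 4 libraries on a logarithmic axis, with exact 95% Poisson intervals. Col6a2 lies at 125 and 514 CPM in wild type and at 4.05 and 2.16 CPM in Col6a2-KO, while Col6a1 and Col6a3 stay within 1.35-fold between genotypes.

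Neutrophils were the most numerous class in each library and made up a smaller part of the cells in the knockout at day 1. They were 66.1% (64.8 to 67.3) of wild-type and 47.0% (45.8 to 48.2) of Col6a2-KO cells at day 1, and 72.3% (71.4 to 73.1) and 74.2% (73.3 to 75.1) at day 3. At day 1, knockout cells included more fibroblasts (17.6% against 9.80%), endothelial cells (854 of 6583 against 258 of 5501), dendritic cells (4.12% against 1.00%) and osteoblast, cementoblast or odontoblast cells (3.04% against 0.782%). The ratio of dendritic cell shares, 4.12 here, was 2.27 with at least 500 genes, 2.54 with a mitochondrial limit of 20%, 2.65 with a limit of 5%, 2.18 at Leiden resolution 0.5 and 2.81 without doublet removal. The last class is not cleanly separated from fibroblasts. Its clusters 7.2, 7.5 and 7.7 had 6, 5 and 5 fibroblast markers among the 10 genes furthest above the median cluster, against 3, 3 and 4 of their own. Of its day 1 cells, 106 of 200 knockout cells and 1 of 43 wild-type cells lay in cluster 7.7, with a median depth of 977 UMIs. Epithelial cells were fewer in Col6a2-KO on both days, at 1.25% against 4.82% and 0.641% against 2.97%. Mural cells were more numerous in Col6a2-KO on both days, at 1.44% (1.17 to 1.76) against 0.618% (0.428 to 0.863) and 1.14% (0.934 to 1.38) against 0.509% (0.380 to 0.669).

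Because neutrophils set every other share, the classes were also taken among non-neutrophil cells. There, endothelial cells were 24.5% of Col6a2-KO and 13.8% of wild-type cells at day 1, and 26.6% and 23.8% at day 3, while fibroblasts were 33.3% and 28.9%, then 13.8% and 12.7%. Monocytes and macrophages, which were 7.35% of all Col6a2-KO and 6.25% of all wild-type cells at day 1, turned to 13.9% and 18.4% on this base. Epithelial cells kept their order at 2.35% and 14.2% at day 1 and 2.48% and 10.7% at day 3. Mural cells were 2.72% (2.21 to 3.32) of Col6a2-KO and 1.82% (1.26 to 2.54) of wild-type cells at day 1, where the intervals overlapped. At day 3 they were 4.42% (3.63 to 5.32) and 1.84% (1.37 to 2.41). Osteoclasts, the cells that resorb bone, depended on the clustering. Here their cluster held 0 cells at day 1, 13 wild-type cells (0.130%, 0.0692 to 0.222) and 9 Col6a2-KO cells (0.0978%, 0.0447 to 0.186) at day 3. At Leiden resolution 0.5 the cluster of that name held 0 and 79 cells of wild type and Col6a2-KO at day 1 and 40 and 24 at day 3, with a median depth of 851 UMIs. With a mitochondrial limit of 5% it held 4, 86, 39 and 31. With 500 genes, a limit of 20% or no doublet removal no cluster took the name. Erythroid cells were 1.64% of wild-type and 0.441% of Col6a2-KO cells at day 1 (0.269-fold). With at least 500 genes per cell the cluster of that name gave 1.13-fold, but it was unlike the cluster here. Its median depth was 2277 UMIs against 11390, its leading genes included Cxcr2, and neutrophil was its second-ranked class. Enzymatic digestion and the yield of each pool can set all of these shares.

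**Figure D2:**
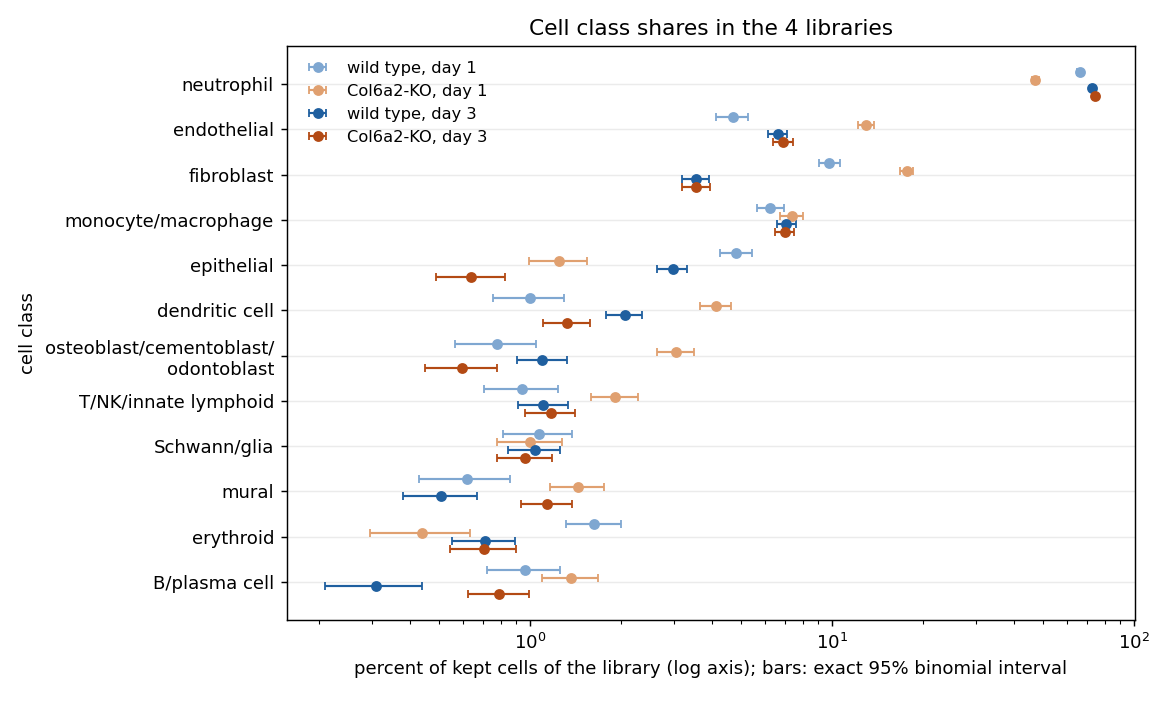
Share of kept cells in each named class for the 4 libraries, in percent on a logarithmic axis, with exact 95% binomial intervals. Neutrophils run from 47.0% to 74.2%, and epithelial cells lie lower and mural cells higher in Col6a2-KO on both days.

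In fibroblasts the medians of metabolic, secretory and matrix gene groups differed between knockout and wild type at day 1. These medians did not hold the same difference at day 3, and the change between the days was not tested. Genes of glycolysis and the hypoxia response were lower in Col6a2-KO at day 1, with a median log2 ratio of -0.73 ± 0.14 over 27 members, 16 of them at least 1.5-fold lower and 0 higher. At day 3 the median was 0.41 ± 0.07, with 4 members higher and 1 lower. Bnip3, a hypoxia-induced mitophagy receptor, stood at 148 and 42.5 CPM in wild type and Col6a2-KO at day 1 and at 54.5 and 89.8 CPM at day 3. Within fibroblast cluster 5 alone, a subset chosen after seeing the data, the day 1 median was -0.46. Egln3, an oxygen sensor, was lower on both days (log2 ratios -2.37 and -1.19), and Ankrd37 on day 1 only (-1.22 and 0.88).

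The unfolded protein response, which handles misfolded protein in the secretory pathway, had a lower median in day 1 knockout fibroblasts, with most members within 1.5-fold. It was -0.46 ± 0.06 at day 1 (24 members, 9 lower and 0 higher) and 0.15 ± 0.08 at day 3 (2 higher and 0 lower). The chaperone Hspa5 stood at 2551 CPM in wild type and 1028 CPM in Col6a2-KO at day 1 and at 726 and 875 CPM at day 3. Sdf2l1 and Creld2 moved alike, at -1.32 and -0.92 on day 1 and 0.78 and 0.54 on day 3. These ratios are over the whole class and were not separated from its cluster make-up.

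Small leucine-rich proteoglycans and other matrix glycoproteins were higher in day 1 knockout fibroblasts, with a median of 0.78 ± 0.09 (28 members, 17 higher and 2 lower), against -0.06 ± 0.06 at day 3 (1 higher, 3 lower). Fmod, which binds fibrillar collagen, stood at 15.1 and 41.6 CPM in wild type and Col6a2-KO at day 1 and at 159 and 84.4 CPM at day 3. Mfap4 (1.64 and -0.37), Fbln5 (1.64 and -0.16) and Vcan (1.28 and -0.97) showed the same turn between the days. All of these ratios are over the whole class and were not separated from its cluster make-up. At day 1 cluster 5 held 320 of 539 wild-type and 204 of 1161 knockout fibroblasts, and cluster 7.0 held 24 and 337. Fibrillar collagens and their processing enzymes differed less, at 0.26 ± 0.07 (25 members, 6 higher and 3 lower) and 0.10 ± 0.05 (0 higher and 0 lower). Col3a1 (2398 and 4536 CPM, then 6753 and 7453 CPM) and Loxl3, a lysyl oxidase, were higher at day 1 (0.92 and 0.92) and not by 1.5-fold at day 3 (0.14 and -0.43), and Col5a3 and P4ha1, a prolyl hydroxylase, were lower at day 1 (-0.90 and -1.02) and not at day 3 (0.24 and 0.07).

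Cell cycle genes were higher in knockout fibroblasts at day 1, at a median of 1.53 ± 0.29 (30 members, 27 higher and 0 lower), while at day 3 they went both ways (0.19 ± 0.18, 2 higher and 3 lower). Bub1, Tk1, Stmn1 and Ccnb1 had log2 ratios of 3.63, 3.27, 2.74 and 2.66 at day 1, and 27 of the 49 day 1 knockout UMIs of Ccnb1 lay in 1 cell. Within cluster 5 alone the medians turned to -0.39 and -1.33, and the day 1 median was 0.66 with a mitochondrial limit of 20% and 0.73 without doublet removal. The day 3 median was -0.08 with mixed clusters divided from another random start. The median of mineralization genes was lower in Col6a2-KO at day 3, at -0.57 ± 0.12 (17 members, 1 higher and 8 lower), against 0.21 ± 0.22 at day 1. That day 3 median was -0.14 over cells with a Y-linked UMI and -0.33 within cluster 5. Spp1, osteopontin, was lower on both days (2782 and 585 CPM, then 7992 and 3224 CPM). Ibsp, bone sialoprotein, stood at 356 and 138 CPM at day 1 and 1464 and 429 CPM at day 3, with 604 of its 821 knockout day 1 UMIs and 2096 of its 4218 wild-type day 3 UMIs in 1 cell. Enpp1 (-2.39 and -0.12) and Bmp2 (-1.51 and 0.97) were lower at day 1 only.

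Matrix proteases and their inhibitors showed no common direction at day 1 (0.10 ± 0.27, 27 members, 4 higher and 11 lower) or day 3 (0.05 ± 0.09). Among them, Mmp10 (-3.26 and 0.38), Plau (-2.37 and 0.09), Plaur (-1.96 and 0.47) and Mmp3 (-1.83 and 0.22), which degrade matrix or activate plasmin, were lower in Col6a2-KO at day 1 only. Mmp10 stood at 3129 and 327 CPM at day 1 and 2192 and 2845 CPM at day 3. Mmp3 and Mmp10 were the leading genes of cluster 5. That cluster held 320 of 539 wild-type and 204 of 1161 knockout fibroblasts at day 1, and 160 of 354 and 166 of 327 at day 3. The ratios of these genes are over the whole class, and a part of cluster make-up in them was not tested. Pro-inflammatory cytokines went both ways (0.14 ± 0.26, 7 higher and 7 lower of 18 at day 1, and 0.22 ± 0.24, 5 higher and 3 lower, at day 3). Csf2, a growth factor for myeloid cells, had 221 UMIs in 20 wild-type cells and 0 in Col6a2-KO at day 1, at least 88.9-fold lower, and was 4.05-fold higher (2.93 to 5.71) at day 3. NF-kB target genes had a median of -0.56 ± 0.13 at day 1 (25 members, 2 higher and 10 lower) and -0.07 ± 0.16 at day 3, with 10 of the 25 reaching 25% of the level in every other class.

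RNA of other cell types moved with the day 1 fibroblast groups. In the same fibroblasts, endothelial activation genes had a median of 1.55 ± 0.48 (18 members, 15 higher and 1 lower) and neutrophil granule genes 0.92 ± 0.29 (20 members, 13 higher and 1 lower), against 0.23 ± 0.30 and 0.11 ± 0.18 at day 3. Selp, Flt1, Tek and Kdr, which mark endothelium, had day 1 log2 ratios of 5.67, 4.37, 2.84 and 2.71. Cluster 7.6 of this class held 102 knockout and 2 wild-type day 1 cells. Its mean log2 fold was 3.65 for fibroblast and 3.14 for endothelial markers. At Leiden resolution 0.5, a cluster also led by Bbof1 and C2cd2, of 29 Col6a2-KO day 1 cells, was named endothelial. Mixed or endothelial cells within the knockout fibroblast class are therefore not excluded. The knockout day 1 fibroblasts were also the shallowest, and 337 of their 1161 cells lay in the low-depth cluster 7.0, against 24 of 539 in wild type. Cluster 5 held the most wild-type day 1 fibroblasts (320, against 204 in Col6a2-KO).

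Across all genes in fibroblasts, 40 were at least 2-fold higher and 29 lower in Col6a2-KO on both days among 10147 compared (90 and 39 with means over cells). On day 1 alone, 623 were higher and 441 lower of 10892 (450 and 582 with median-of-ratios factors), and on day 3, 78 higher and 138 lower of 9011 (257 and 241 with means over cells). The day 1 and day 3 ratios correlated at 0.0127 ± 0.020 across genes, which are not independent replicates. The median of all genes lay 0.11 above 0 at day 1, and relative to it the day 1 medians were -0.85 for glycolysis and hypoxia, -0.57 for the unfolded protein response, 0.67 for matrix glycoproteins and 1.41 for the cell cycle. Pde4d, a cAMP phosphodiesterase, was among the genes furthest above wild type on both days, at 84.9 and 1913 CPM and then 261 and 1533 CPM, together with Lhfpl4 (2.24 and 36.1, then 1.04 and 40.6 CPM) and Nebl (2.85 and 22.4, then 11.5 and 41.7 CPM). Pclo (2.04 and 28.0, then 14.9 and 97.7 CPM) and Cfap61 (2.04 and 7.92, then 4.51 and 22.6 CPM) also ranked there, and without fibroblast clusters 7.0, 7.6 and 21 their mean log2 ratios of both days turned from 3.21 and 2.09 to -0.06 and -0.01. Catsper2 had 41 of its 44 knockout day 3 UMIs in 1 cell. Ranked lowest on both days by the day nearer to no difference were, besides Col6a2, Rnaset2b (80.6 and 1.69, then 65.9 and 26.2 CPM), Pcdh15 (42.7 and 5.73, then 24.6 and 8.98 CPM), Mgarp (11.4 and 3.20, then 8.67 and 2.52 CPM), Csta3 (26.9 and 3.03, then 3.82 and 0.719 CPM) and Tas1r1, with 133 of its 250 wild-type day 1 UMIs in 1 cell. Snhg3 was among the highest of day 1 (6.11 and 71.0 CPM). Several single-day genes rested on 1 cell: Plin1 and Rasef at day 1 (135 of 136 and 110 of 112 wild-type UMIs) and Trp53cor1 and Rasef at day 3 (145 of 222 and 44 of 49 knockout UMIs). BC028777 (32.6 and 0.719 CPM) and Pmch (42.7 and 4.31 CPM) were lowest at day 3 after Col6a2.

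Monocytes and macrophages of the knockout, taken as a class, held less RNA of most pro-inflammatory cytokines at day 1, and of a few at day 3. The median was -0.90 ± 0.18 at day 1 (15 members, 0 higher and 11 lower) and -0.45 ± 0.12 at day 3 (0 higher and 3 lower), and the day 1 value was -0.39 with a mitochondrial limit of 20% and -0.45 with 500 genes. Nos2, inducible nitric oxide synthase, stood at 343 and 57.3 CPM in wild type and Col6a2-KO at day 1 and 444 and 474 CPM at day 3. Ptgs2, the inducible cyclooxygenase, stood at 1597 and 443 CPM and then 1638 and 1197 CPM. Il6 was lower on both days (-1.15 and -1.18) at a level under 25% of that in another class. The class had another make-up in the 2 day 1 libraries. Cluster 16, with Nos2 and Arg1 among its leading genes, held 166 of 344 wild-type and 110 of 484 knockout cells, while clusters 17 and 3.0 held 82 and 35 wild-type and 161 and 107 knockout cells. Within cluster 16 alone, a subset chosen after seeing the data, the cytokine medians were -0.15 at day 1 and -0.55 at day 3.

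The median of type I interferon response genes in these cells had opposite signs on the 2 days, a contrast that was not tested. It was 0.41 ± 0.19 (31 members, 10 higher and 1 lower) on day 1 and -0.48 ± 0.17 (1 higher and 14 lower) on day 3. Ifit1, an antiviral RNA-binding protein, stood at 50.7 and 138 CPM at day 1 and 264 and 99.7 CPM at day 3. Ifit2 and Usp18 had ratios of 2.84 and 2.72 at day 1 and 0.44 and -0.48 at day 3. Ifi44 went the other way at day 1, with 33 and 53 wild-type UMIs on the 2 days and 0 in Col6a2-KO on both, at least 13.1-fold and 19.7-fold lower. Restricted to cells with a Y-linked UMI, the day 3 median was -0.24. Chemokines went both ways on each day, with medians of 0.36 ± 0.15 (19 members, 5 higher and 5 lower) and -0.27 ± 0.08 (2 higher and 4 lower), with the day 1 median at 0.16 at Leiden resolution 0.5 and 0.11 within cluster 16, and the day 3 median at -0.10 over cells with a Y-linked UMI. Ccl5, which attracts T cells, had ratios of 2.68 at day 1 and -0.27 at day 3, and Cxcl5 was lower on both days (-2.18 and -0.58). Cxcl13 was higher in Col6a2-KO, with 136 of its 149 UMIs at day 1 and all of its 17 UMIs at day 3 in 1 cell.

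In knockout monocytes and macrophages, as in fibroblasts, the median of glycolysis and hypoxia genes was lower at day 1 (-0.44 ± 0.09, 26 members, 0 higher and 9 lower). Most members lay within 1.5-fold, and the day 3 median was 0.05 ± 0.06. Within cluster 16 alone the day 1 median was -0.0971. Bnip3, Ero1l and Pfkfb3 had day 1 ratios of -1.60, -1.38 and -1.25. Antigen presentation genes were at 0.21 ± 0.16 (22 members, 7 higher and 2 lower) and -0.36 ± 0.09 (0 higher and 5 lower), with H2-DMb1 at 1.26 and -0.64 and Tap1 at 0.73 and -0.72. Cell cycle genes had a median of 0.27 ± 0.41 at day 1 and 0.49 ± 0.39 at day 3 (16 members, 7 higher and 1 lower at day 3). The day 3 median was -0.29 with means over cells. Ube2c (2.98 and 3.51) and Birc5 (1.77 and 1.89) were higher on both days, while Ccnb1 had 97 wild-type UMIs at day 1, all in 1 cell. NF-kB target genes differed little (-0.20 ± 0.09 and -0.06 ± 0.08, with 0 of 27 higher and 1 and 0 lower). Hemoglobin RNA in this class was higher in Col6a2-KO at day 1, at 1.55 ± 0.26, and at -0.20 ± 0.12 at day 3.

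In this class 14 genes were at least 2-fold higher and 12 lower on both days of 6011 compared. On day 1, 125 were higher and 180 lower of 5665 (304 and 233 with means over cells), and on day 3, 61 and 76 of 6310. The ratios of the days correlated at 0.0872 ± 0.021 across genes. Pde4d was highest by the day nearer to 0 (48.8 and 1254 CPM, then 32.1 and 821 CPM), followed by Lhfpl4 (16.9 and 193, then 0.459 and 36.3 CPM). Exoc3l2 and Top2a, a DNA topoisomerase of dividing cells, were also higher (9.75 and 39.3, then 6.88 and 40.8 CPM; 9.10 and 26.8, then 5.05 and 20.2 CPM), and the mean log2 ratio of Top2a over both days turned from 1.74 to -0.26 with a mitochondrial limit of 20%, -0.06 with 500 genes and -0.21 within cluster 16. The mast cell proteases Cma1 and Mcpt4 had 121 and 113 UMIs in 33 and 36 knockout cells at day 1 and 0 in wild type, at least 33.9-fold and 31.6-fold higher. Mast cells and basophils were a class with fixed markers, but no cluster took that name. The level of these genes could thus not be compared with that of a mast cell class. Mast cells within the monocyte and macrophage class are not excluded. Rnaset2b (59.2 and 4.37, then 60.5 and 16.5 CPM), Rusc2 (41.0 and 16.9, then 38.5 and 9.48 CPM), Wdfy1 (26.7 and 7.64, then 21.6 and 9.89 CPM), Tll2 (39.7 and 16.9, then 38.5 and 18.1 CPM), Taco1 and Arhgef40 were lower on both days. At day 1 Hamp, Saa1 and Arhgef40 were lowest, with 126 of 132, 183 of 301 and 91 of 99 wild-type UMIs in 1 cell. At day 3 Il1f6, the cytokine IL-36 alpha, was 12.6-fold higher (5.14 to 39.9) and Cxcl9, an interferon-induced chemokine, 3.55-fold lower (2.94 to 4.31), and Cxcl9 was higher (1.35) over cells with a Y-linked UMI. Trp53cor1 was also higher at day 3, with 36 of its 51 knockout UMIs in 1 cell.

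Neutrophils of the knockout, taken as a class, held more RNA of granule proteins and less of cytokines at day 1. Granule proteins are made in the bone marrow before neutrophils mature. Granule genes were at 0.63 ± 0.06 (29 members, 16 higher and 0 lower) on day 1 and 0.27 ± 0.06 (7 higher and 0 lower) on day 3. Fcnb was higher on both days (0.763 and 3.96, then 1.36 and 4.24 CPM), Chil3 likewise (40.1 and 93.9, then 19.7 and 33.7 CPM), and Prtn3 mainly at day 1 (2.20 and 0.34). Pro-inflammatory cytokines were at -0.70 ± 0.30 (18 members, 2 higher and 10 lower) at day 1 and -0.04 ± 0.04 at day 3, with Lif at -1.23 and 0.36 and Il12a at -0.98 and -0.45. Anti-inflammatory and resolution genes were at -0.29 ± 0.09 (13 members, 0 higher and 3 lower) and 0.08 ± 0.06. NF-kB target genes differed little as a group (-0.13 ± 0.07 and -0.20 ± 0.04, with 2 of 26 lower and 2 higher at day 1 and 3 lower and 0 higher at day 3), with Traf1 at -1.04 and -0.30 and Tnfaip3, an NF-kB inhibitor, at -0.67 and -0.27.

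The median of all neutrophil genes lay 0.27 above 0 at day 1, and relative to it the day 1 medians were 0.36 for granule genes, -0.96 for cytokines, -0.56 for anti-inflammatory genes and -0.40 for NF-kB targets. Most wild-type day 1 neutrophils lay in cluster 4 (1557, led by Ccl3 and Il1a) and cluster 1 (973). Most knockout ones lay in cluster 1 (1317) and cluster 12 (631). Cluster 13, led by Camp and Ngp, held 15 wild-type and 68 knockout cells at day 1, and 39 and 42 at day 3. Chil3 and Fcnb were among its leading genes, and its part in the granule gene ratios was not tested. Within cluster 1 alone the day 1 medians of granule genes, cytokines and NF-kB targets were 0.04, 0.04 and 0.10. The cytokine median was also -0.24 with no UMI minimum and -0.27 with a pseudocount of 5 UMIs. In the same neutrophils, fibrillar collagen genes (0.69 ± 0.27), matrix glycoproteins (0.82 ± 0.45) and endothelial activation genes (0.80 ± 0.36), which these cells should lack, were higher in Col6a2-KO at day 1 and at -0.26 ± 0.20, -0.35 ± 0.18 and -0.08 ± 0.08 at day 3.

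Among 8210 neutrophil genes, 27 were at least 2-fold higher and 43 lower on both days (20 and 56 with median-of-ratios factors). On day 1, 433 were higher and 226 lower of 7411 (164 and 365 with these factors), on day 3, 103 and 146 of 8850, and the days correlated at 0.267 ± 0.017 across genes. Tagap1 (0.339 and 14.5, then 0.707 and 13.5 CPM), Dlgap5 (0.254 and 7.23, then 0.884 and 4.18 CPM), Prph (1.02 and 4.78, then 1.12 and 7.13 CPM) and Id2, a transcriptional inhibitor (106 and 286, then 97.0 and 238 CPM), were higher on both days. Gbp2b, a guanylate-binding protein, was lower, with 93 and 532 wild-type UMIs on the 2 days and 1 knockout UMI on each, a ratio of 57.7 (10.1 to 2305) and 532 (95.1 to 21065). Esd, S-formylglutathione hydrolase, stood at 465 and 194 CPM and then 546 and 215 CPM, and Ntng2 at 49.7 and 21.3 and then 40.0 and 14.6 CPM, with Unc93a2, Samd13 and Armc4 also lower. At day 1 alone Cdk5rap1 was lower (254 and 8 UMIs) and Hist1h1b, a linker histone, higher (7 and 85 UMIs, 41 of the latter in 1 cell), and 220 of the 305 wild-type UMIs of Zfp444 lay in 1 cell. At day 3 Il1f6 was 13.2-fold higher (9.75 to 18.2).

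Endothelial cells of the knockout held less RNA of cell cycle genes at day 1, and about the wild-type amount at day 3. The median was -1.03 ± 0.30 (30 members, 1 higher and 18 lower) at day 1 and 0.19 ± 0.08 (2 higher and 0 lower) at day 3. Mki67, a proliferation marker, stood at 26.1 and 4.33 CPM and then 46.1 and 36.8 CPM, and Cenpf, a kinetochore protein, at 16.8 and 1.12 CPM and then 62.4 and 49.2 CPM. Kif11 and Tk1 had day 1 ratios of -2.93 and -2.91. Of the wild-type day 1 UMIs, 32 of 70 for Mki67 and 28 of 45 for Cenpf lay in 1 cell. The day 1 median was -0.50 with means over cells, and the day 3 median -0.49 over cells with a Y-linked UMI.

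Interferon response genes of endothelial cells had a median of -0.32 ± 0.21 at day 1 (30 members, 3 higher and 12 lower). At day 3 it was -0.15 ± 0.10 (1 higher and 5 lower). Members went both ways at day 1, with Gbp3 at -2.20 and -0.58 on the 2 days and Cmpk2 at 2.24 and 0.35. Heat-shock and dissociation response genes had a median of 0.30 ± 0.06 at day 1, where only 2 of 26 members were 1.5-fold higher and 0 lower, and -0.02 ± 0.04 at day 3. TGF-beta target genes were at -0.12 ± 0.11 and 0.18 ± 0.07, with Tagln, a smooth muscle protein, higher on both days (1.85 and 1.85) and Ccn2 at -1.65 and 0.65. Tagln was the leading gene of the mural cluster, and RNA of mural cells within this class is not excluded. Chemokines had a median of -0.48 ± 0.62 at day 1, a range that includes 0 (15 members, 0 higher and 7 lower), and -0.13 ± 0.13 at day 3 (2 higher and 5 lower). Among them was Ccl2, which attracts monocytes, at 1607 and 216 CPM and then 234 and 395 CPM. Endothelial activation genes differed little (0.07 ± 0.07 and -0.09 ± 0.05, with 1 and 0 of 25 lower and 1 and 2 higher). Hemoglobin RNA in this class was at 1.59 ± 0.29 and -0.83 ± 0.05.

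Of 10172 endothelial genes, 10 were at least 2-fold higher and 22 lower on both days. On day 1, 103 were higher and 229 lower of 9440 (303 and 396 with means over cells), on day 3, 67 and 87 of 10686, and the days correlated at 0.110 ± 0.025 across genes. Lhfpl4 (0.372 and 273, then 0.323 and 19.1 CPM), Pde4d (95.7 and 2086, then 160 and 1772 CPM), Alad (28.3 and 56.3, then 18.6 and 52.4 CPM), Uggt2 and Map3k6 were higher on both days, as was Slc44a4 with 50 of 54 and 97 of 105 knockout UMIs in 1 cell. Gbp2b had 18 and 89 wild-type UMIs and 0 in Col6a2-KO, at least 13.9-fold and 32.0-fold lower. Rnaset2b (77.8 and 1.60, then 55.0 and 16.8 CPM), Wdfy1 (65.2 and 18.8, then 68.6 and 22.5 CPM), Mdga2 (10.4 and 1.76, then 11.0 and 3.30 CPM), Oxnad1 (26.4 and 5.45, then 4.85 and 1.95 CPM) and Gal, the neuropeptide galanin (242 and 97.2, then 544 and 203 CPM), were lower on both days. The day 1 extremes Ccl21a, Cep72, Prl2c5 and Dennd2a had 451 of 451, 153 of 165, 86 of 117 and 84 of 119 UMIs of their higher library in 1 cell. At day 3 Cxcl9 was 22.4-fold lower (17.7 to 28.7), with 706 of its 1539 wild-type UMIs in 1 cell.

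**Figure D3:**
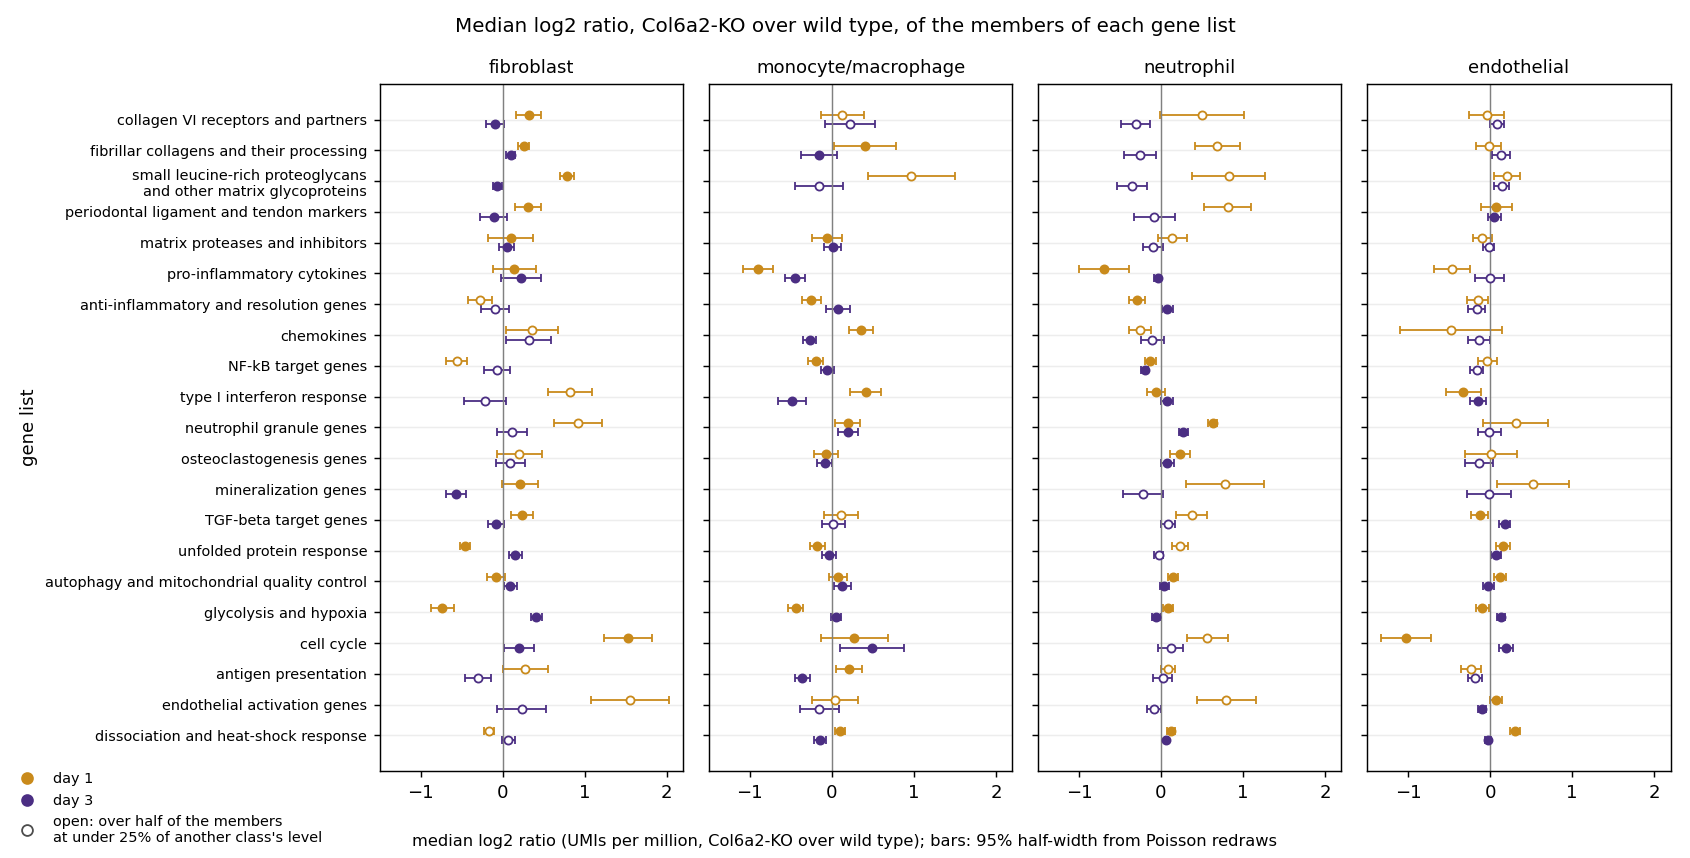
Median log2 ratio of Col6a2-KO over wild type for the gene lists in 4 cell classes at day 1 (orange) and day 3 (purple). Bars are 95% half-widths from Poisson redraws. Open markers are lists with most members at under 25% of another class's level. Fibroblast glycolysis and hypoxia genes lie at -0.73 and 0.41, and endothelial cell cycle genes at -1.03 and 0.19.

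Setting members without a UMI in a library to their bound, or leaving them out where no bound could be given, moved the day 1 medians of neutrophil granule genes to 0.61 and of endothelial interferon genes to -0.37. It moved the day 3 median of granule genes in fibroblasts to 0.12 and left the other genotype medians given here as they were.

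Between day 1 and day 3, interferon response genes were higher at day 3 in neutrophils and endothelial cells of both genotypes. In neutrophils the median log2 ratio of day 3 over day 1 was 0.72 ± 0.11 in wild type (33 members, 23 higher and 0 lower) and 0.94 ± 0.12 in Col6a2-KO (23 higher and 0 lower), and in cluster 1 alone the values were -0.16 and 0.22. The class had another make-up on the 2 days. Cluster 2, led by interferon-induced genes such as Rsad2 and Isg15, held 83 wild-type and 190 knockout cells at day 1 and 928 and 1270 at day 3, while the wild-type cells of cluster 4 were 1557 and then 335. In endothelial cells it was 1.07 ± 0.21 (30 members, 24 higher and 0 lower) and 1.18 ± 0.17 (26 higher and 0 lower), with Cmpk2 at 4.22 and 2.33 and Zbp1, a nucleic acid sensor, at 2.70 and 0.83. Endothelial cell cycle genes were higher at day 3, at 1.48 ± 0.26 in wild type (21 higher and 1 lower of 30) and 3.07 ± 0.27 in Col6a2-KO (24 higher and 0 lower), with Mki67 at 0.81 and 3.06. The median of endothelial unfolded protein response genes was lower at day 3, with most members within 1.5-fold (-0.41 ± 0.10 and -0.49 ± 0.06, with 7 and 8 of 24 lower and 0 higher). That of heat-shock and dissociation genes was also lower (-0.33 ± 0.08 and -0.65 ± 0.06, 7 and 15 of 26 lower and 0 higher).

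Fibroblasts, taken as a class, held more RNA of the matrix at day 3 in both genotypes. Their make-up differed between the days as well. Cluster 5 held 320 of 539 wild-type and 204 of 1161 knockout cells at day 1 and 160 of 354 and 166 of 327 at day 3. Cluster 7.3 held 36 and 104, then 83 and 54, and cluster 7.0 held 24 and 337, then 9 and 1. Fibrillar collagen genes were at 1.00 ± 0.13 in wild type (25 members, 15 higher and 2 lower) and 0.65 ± 0.10 in Col6a2-KO (14 higher and 1 lower), and matrix glycoproteins at 1.03 ± 0.06 (28 members, 21 higher and 1 lower) and 0.54 ± 0.07 (13 higher and 5 lower). Within cluster 5 alone these medians were 1.37 and 0.54, and 1.60 and 0.53. Collagen VI receptors and partners were at 0.90 ± 0.26 (13 members, 8 higher and 0 lower) and 0.58 ± 0.13 (6 higher and 0 lower), periodontal ligament and tendon markers at 0.83 ± 0.14 and 0.45 ± 0.15, and TGF-beta targets at 0.30 ± 0.09 and 0.24 ± 0.18. Col3a1 (1.49 and 0.72), Fmod (3.39 and 1.02), Bgn (1.12 and 0.09), Tgfbi (2.46 and 0.57) and S100a4 (3.47 and 1.94) all had the larger ratio in wild type. Fibroblast cell cycle genes were at 2.21 ± 0.29 in wild type (30 members, 22 higher and 0 lower) and 0.43 ± 0.24 in Col6a2-KO (14 higher and 5 lower). The wild-type value was 0.80 with a mitochondrial limit of 20%, and the Col6a2-KO value turned to -0.09 without each gene's highest cell and to -0.01 with mixed clusters divided from another random start. In monocytes and macrophages, where the median of all wild-type genes lay at -0.14, glycolysis and hypoxia genes were at 0.13 ± 0.07 in wild type and 0.77 ± 0.09 in Col6a2-KO (2 and 18 of 26 higher, 0 lower), with Nos2 at 0.37 and 3.04 and Bnip3 at -0.21 and 1.63. Relative to that median the wild-type value was 0.27, and it was -0.04 over day 3 cells with a Y-linked UMI. Cluster 16 held 166 of 344 wild-type and 110 of 484 knockout cells of the class at day 1, and 509 of 706 and 477 of 641 at day 3. Within cluster 16 alone the glycolysis and hypoxia medians over time were -0.0471 and 0.00918, and those of cytokines -0.0449 and -0.53. Over the class, cytokines were at 0.27 ± 0.11 and 0.44 ± 0.13, the latter turning to -0.03 with a mitochondrial limit of 20%, chemokines at -0.39 ± 0.25 and -0.40 ± 0.10, turning to 0.14 in wild type with a minimum 4 times higher and to 0.07 in Col6a2-KO over cells with a Y-linked UMI, and matrix proteases at 0.13 ± 0.18 and 0.27 ± 0.23, with Mmp13, a collagenase, at 0.86 and 3.47 and Ctsk, the collagen-degrading cathepsin K, at 1.52 and 2.59.

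At least 2-fold higher and lower at day 3 in both genotypes were 145 and 120 genes in neutrophils, 51 and 68 in monocytes and macrophages (78 and 44 with median-of-ratios factors), 167 and 126 in fibroblasts (250 and 109 with means over cells) and 236 and 81 in endothelial cells. Rtkn and Xlr5a were higher at day 3 in neutrophils and in monocytes and macrophages, Lrp1b in fibroblasts and in monocytes and macrophages, and Cxcl9 in endothelial cells (0.372 and 249 CPM in wild type, 0.321 and 11.1 in Col6a2-KO). Fibroblasts also held more Lrrc15 (4.07 and 40.2, 7.59 and 59.7 CPM), Ereg, an EGF-family ligand (3.46 and 42.3, 5.06 and 41.3 CPM), and Cp, ceruloplasmin (16.7 and 178, 20.1 and 123 CPM). Lower at day 3 were Gphn in neutrophils and in monocytes and macrophages, Chil3 in monocytes and macrophages (369 and 67.4, 862 and 98.5 CPM), Bc1, a neuronal noncoding RNA, in fibroblasts (266 and 4.51, 228 and 3.59 CPM) and endothelial cells (302 and 7.12, 199 and 2.10 CPM), and Klhl24 in fibroblasts (523 and 29.5, 289 and 32.3 CPM). Each day of a genotype was 1 library, so these day differences were not separated from differences between libraries.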

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

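The tests weighed here were all chosen after the results they bear on had been seen. A signal outside the main measurement was found in the counts of the bacterial beta-galactosidase reporter tg_LacZ. It had 28 UMIs in Col6a2-KO at day 1 and 36 in Col6a2-KO at day 3 over all barcodes, and 0 in both wild-type libraries. In Col6a2-KO fibroblasts it had 21 UMIs in 20 cells at day 1 and 22 UMIs in 17 cells at day 3, and in mural cells 2 and 11 UMIs. Neutrophils and endothelial cells held 0 on both days. No explanation of this signal was tested.

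Several gene groups had medians of opposite sign between genotypes at day 1 and day 3, and these differences between the days were not tested, as each group is 1 library. A median can turn while few members do, and not every turn held in the alternatives. In monocytes and macrophages the median log2 ratio of Col6a2-KO over wild type was 0.36 at day 1 and -0.27 at day 3 for chemokines, with 5 of 19 higher and 5 lower at day 1, and 0.41 and -0.48 for the type I interferon response. In fibroblasts it was -0.73 and 0.41 for glycolysis and hypoxia genes, and -0.46 and 0.15 for the unfolded protein response, with 2 of 24 higher at day 3. In endothelial cells it was -1.03 and 0.19 for cell cycle genes, with 2 of 30 higher at day 3 and a day 3 median of -0.49 over cells with a Y-linked UMI and no Xist UMI.

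The first pattern weighed is that 9 of 8966 genes were at least 2-fold apart between genotypes on both days in 3 or more of the 4 classes, Snhg3, Gm42743, Lhfpl4, Pde4d and Dynlt1b higher in Col6a2-KO and Wdfy1, Krt17, Gm43305 and Rnaset2b lower. Sequence around Col6a2 carried over from the strain of the targeted cells is argued against, as 0 of the 9 lie within 20 Mb of it. Other stretches of the genome that differ between the mouse lines could contribute, since among 24 genes apart in 2 or more classes 8 had another within 5 Mb, at percentile 98.1 of random gene sets. Free RNA from 1 class seen in the others is also not ruled out, as only 2 of the 9 reached 25% of their highest level in 3 or more main classes. Krt17 was highest in epithelial cells (7769 CPM in wild type at day 3) and under 25% of that in every main class. Gm42743, Pde4d, Dynlt1b and Gm43305 were highest in B and plasma cells and Wdfy1 in osteoclasts, classes of few cells. For these genes the count cannot tell free RNA from a class's own RNA. A response to the loss of Col6a2 itself stays open, since every comparison has the same 2 lines.

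The second pattern is that 22 of 6828 genes were at least 2-fold apart between the days in both genotypes in all 4 classes, 11 higher and 11 lower at day 3. Reads within introns of long genes, counted at another rate in the day 3 libraries, may account for part of it, as the genes higher at day 3 had a median span of 74.5 kb, at percentile 99.6 of expression-matched sets. A ligature response common to all classes could not be told from the fixed lists, which held 0 of the 22 genes. Both explanations stay open.

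The third pattern is the number of fibroblast genes at least 2-fold apart between genotypes at day 1, 1064. To keep the choice of genes apart from the tests, 761 genes were chosen in randomly drawn cells and looked at in the cells not drawn, where the median log2 ratio in the direction of the drawn cells was 1.14 (738 genes with enough UMIs, 427 of them 2-fold apart). Clusters 7.0, 7.6 and 21, which hold mostly Col6a2-KO day 1 cells, are argued against as the whole source, as the median was 1.05 ± 0.04 without them (699 genes, 373 of them 2-fold apart). Another make-up of fibroblast clusters is argued against as the whole cause for the 422 genes with enough UMIs in cluster 5. Their median was 0.87 ± 0.06 within that cluster, with 197 of them 2-fold apart. The need for UMIs in cluster 5 can leave out genes carried by other clusters. Of the other 339, 280 were higher and 59 lower in Col6a2-KO in the drawn cells. Their summed UMIs gave 0.57 ± 0.14 within cluster 5, which leaves make-up open for these. A partial contribution of either to the genes apart stays open too. Free RNA from other classes stays open. Fibroblasts had the highest level of all named classes for 26.0% (23.4 to 28.8) of the 1064 genes, in the library where these were higher. That share cannot tell either way, as none is given for genes not apart. An effect of the genotype and a difference between the 2 preparations stay open.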

How the results depend on the processing

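The alternatives that left out each gene's highest cell, kept only some clusters, divided mixed clusters from another random start, or kept only day 3 cells with a Y-linked UMI and no Xist UMI were chosen after seeing the data, as were all alternatives for the list medians over time. No paired analysis was possible because no test was run and the replicate numbers in the labels follow the day. Of 68 list medians, 65 stayed within their counting error at Leiden resolution 0.5, 67 at resolution 2, 59 without doublet removal, 64 at a mitochondrial limit of 5%, 66 with a pseudocount of 5 UMIs, 52 with median-of-ratios factors, 44 with means over cells and 64 from another random start. With 500 genes 55 did so, without genes under 25% of another class's level 51, and over day 3 cells with a Y-linked UMI 53. Within single clusters fewer did, 5 of 14 in fibroblasts of cluster 5, 3 of 12 in neutrophils of cluster 1 and 15 of 24 in monocytes and macrophages of cluster 16. Of 144 named genes, 142 stayed so at Leiden resolution 0.5, 142 at resolution 2, 133 without doublet removal, 132 with 500 genes, 122 over cells with a Y-linked UMI and 107 with means over cells. No alternative is a replicate, intervals cover counting error alone, and shallow classes limit genes with few UMIs. Unless stated, the cause of a moved or reversed value was not tested.

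With no minimum beyond 1 UMI, which admits genes with few counts by construction, genes apart on both days were 974 in neutrophils, 1111 in monocytes and macrophages, 1193 in fibroblasts and 852 in endothelial cells. Day 1 counts in that class order were 6129, 5841, 6890 and 4663, day 3 counts 6704, 6005, 5306 and 5002, and counts between days 1819, 1713, 1468 and 1614. The correlation of the days was 0.0407 in neutrophils, 0.0401 in monocytes and macrophages and 0.0311 in endothelial cells. The day 3 median of anti-inflammatory genes in neutrophils turned from 0.08 to -0.0466, and that of fibrillar collagens in monocytes and macrophages at day 1 from 0.40 to -0.00320. Fibroblast lists outside the central range of random lists at day 3 were 5, against 8.

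A minimum 4 times higher, which compares fewer genes by construction, gave 32, 5, 22 and 13 genes apart on both days in the same class order. Day 1 counts were 210, 103, 437 and 78, day 3 counts 85, 23, 53 and 40, and counts between days 98, 37, 131 and 117. Correlations were 0.344 in neutrophils and 0.178 in monocytes and macrophages. Fibrillar collagens in monocytes and macrophages at day 1 were again at -0.00320 and wild-type chemokines of that class over time at 0.14. Fibroblast cell cycle genes turned to -0.14 at day 3 and to -0.24 over time in Col6a2-KO.

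Leaving out genes under 25% of another class's level also compares fewer genes. Genes apart on both days were 34 in neutrophils and 20 in endothelial cells, at day 1 they were 249 and 211, and at day 3 106 and 97. Neutrophil genes apart between days were 165, with a correlation of 0.324. Lists outside the central range were 5 and 2 in neutrophils at day 1 and day 3, against 11 and 4, 7 and 5 in endothelial cells, against 11 and 8, and 5 in monocytes and macrophages at day 1, against 8. Day 1 fibrillar collagens in monocytes and macrophages turned to -0.20 and day 1 glycolysis and hypoxia genes in endothelial cells to 0.0394. Fibroblast cell cycle genes turned to -0.12 at day 3 and to -0.14 over time in Col6a2-KO.

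Within neutrophils of cluster 1, 23 genes were apart on both days, 160 at day 1, 92 at day 3 and 56 between days, and the correlation was 0.195. Day 1 cytokines turned from -0.70 to 0.0382, day 1 NF-kB targets from -0.13 to 0.10, and wild-type interferon genes over time from 0.72 to -0.16. Lists outside the central range were 2 at day 1 and 1 at day 3. Within monocytes and macrophages of cluster 16 the correlation was 0.131 and 3 lists lay outside the central range at day 1. There cytokines over time turned to -0.0449 in wild type and -0.53 in Col6a2-KO, wild-type glycolysis and hypoxia genes over time to -0.0471, and Top2a to -0.21. Over day 3 cells with a Y-linked UMI, neutrophil genes apart were 153 at day 3 and 164 between days. Correlations were 0.234, 0.123, 0.0741 and 0.142 in neutrophils, monocytes and macrophages, fibroblasts and endothelial cells. In monocytes and macrophages the Col6a2-KO chemokines over time turned to 0.0731, wild-type glycolysis and hypoxia genes over time to -0.0357, and Cxcl9 at day 3 from -1.83 to 1.35. Endothelial cell cycle genes at day 3 turned to -0.49, and 5 fibroblast lists lay outside the central range at day 3.

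With at least 500 genes per cell, 16 genes were apart on both days in monocytes and macrophages, with a correlation of 0.0374 and 5 lists outside the central range at day 1. In that class day 1 granule genes turned from 0.19 to -0.11 and Top2a on both days from 1.74 to -0.0599. The fibroblast correlation was 0.0500, and 7 neutrophil lists lay outside the central range at day 3. Endothelial Ccl21a at day 3 turned from -3.97 to 2.33. The ratio of shares at day 1 was 1.13 for the cluster then named erythroid, which was unlike the main one. It was 1.59 for fibroblasts and 0.946 for monocytes and macrophages. Wild-type fibroblast Col6a2 was 112 CPM at day 1 and 345 CPM at day 3. Here a cluster of 210 cells closest to fibroblasts, with Col6a2 among its leading genes, was left unnamed and out of the class.

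With a mitochondrial limit of 20%, 15 genes were apart on both days in monocytes and macrophages, with a correlation of 0.0378. In that class Col6a2-KO cytokines over time turned to -0.0280, day 1 granule genes to -0.0487 and Top2a to -0.26, and the ratio of shares at day 1 was 0.968. With a limit of 5%, correlations were 0.0641 in monocytes and macrophages, 0.0523 in fibroblasts and 0.0656 in endothelial cells, and monocytes and macrophages had 5 lists outside the range at day 3.

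With means over cells, monocytes and macrophages had 537 genes apart at day 1, 252 at day 3 and 200 between days, a correlation of 0.0434, and 5 lists outside the range at day 3, where cell cycle genes turned to -0.29. Fibroblasts had 129 genes apart on both days and 498 at day 3. Endothelial cells had 699 genes apart at day 1 and 272 at day 3, with a correlation of 0.0704. With a pseudocount of 5 UMIs the neutrophil correlation was 0.244. Leaving out each gene's highest cell gave 20 endothelial genes on both days and turned fibroblast cell cycle genes over time in Col6a2-KO to -0.0925.

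Fibroblasts of cluster 5 had 656 genes apart at day 1 and 5 lists outside the range at day 3, with cell cycle genes turned to -0.39 at day 1 and -1.33 at day 3, and Rasef at day 3 from 5.09 to -1.84. Without clusters 7.0, 7.6 and 21, Pclo turned from 3.21 to -0.0639 and Cfap61 from 2.09 to -0.00793 over both days, and Pclo from 3.72 to -0.20 at day 1. Divided from another random start, fibroblasts had 5 lists outside the range at day 3, cell cycle genes turned to -0.0798 at day 3 and to -0.0101 over time in Col6a2-KO, and wild-type Col6a2 was 115 and 419 CPM.

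Without doublet removal, monocytes and macrophages had 14 genes apart on both days, a correlation of 0.0663 and day 1 granule genes at -0.0622, endothelial Ccl21a at day 1 turned from 8.60 to -0.35, and day 1 ratios of shares were 1.00 for monocytes and macrophages and 0.688 for neutrophils. At Leiden resolution 0.5 the former ratio was 1.01, and 5 lists of that class lay outside the range at day 1. Among non-neutrophil cells, day 1 ratios of shares were 0.909 for B and plasma cells, 1.77 for endothelial cells, 1.15 for fibroblasts and 0.753 for monocytes and macrophages, as the removal of neutrophils rescales every share. With classes by per-cell marker score they were 0.842 for B and plasma cells and 0.810 for neutrophils, and 1.16 for neutrophils at day 3. Thinned to 1000 UMIs, which lowers detection by construction, the shares of fibroblasts with Col6a2 were 10.4%, 0.461%, 25.7% and 0.327%.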

Other observations

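The values here were chosen after the data had been seen. Xist was detected in 714 of 9205 cells of Col6a2-KO at day 3 (7.76%, 7.22 to 8.32) and in 2, 2 and 1 cells of wild type at day 1, Col6a2-KO at day 1 and wild type at day 3. Cells with a UMI of a Y-linked gene were 42.2%, 38.8%, 31.5% and 25.1% in wild type and Col6a2-KO at day 1 and wild type and Col6a2-KO at day 3. In Col6a2-KO at day 3, 26 cells held UMIs of both. The ratio of Hba-a1 to Hba-a2 UMIs, 2 alpha-globin genes, was 1.30 and 1.31 in the wild-type libraries and 6.55 and 7.55 in the Col6a2-KO libraries.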
